A study of Arabidopsis thaliana with 6 samples.

How the data were processed

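The series holds 6 one-colour expression arrays of total RNA from Arabidopsis thaliana flowers at stage 15. Per the labels, 3 came from wild-type Columbia plants and 3 from transgenic plants overexpressing miR159a. Each group carries the replicate letters a, b and c. The labels do not say whether the letters stand for separate plants, so p-values measure only the spread between these samples, which may be technical.

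The values are intensities on a linear scale, deposited as 1 signal per probe set and array in a table of 22810 probe sets. The software and the normalisation used upstream are not given in the sources used here. The deposited signals had already been scaled: their mean, after leaving out the lowest and highest 2% on each array, lay between 199 and 200 (199.0 to 199.8) on all 6 arrays. No pair of arrays held identical values, and the correlation between arrays on the log2 scale ran from 0.933 to 0.984 over all probe sets other than controls and from 0.885 to 0.978 over the tested ones. Detection calls were not used here, and the number of arrays limits the precision.

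Signals were put on the scale log2(signal + 16). Fold changes are on that scale, which understates the change of dim probe sets. The array medians spanned 0.16 log2, below the limit set for further normalisation, so none was applied. The 64 control probe sets and the 25% of the others with the lowest mean were left out, which removed 5687 probe sets as dim and left 17059 tested. Each was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from this fit unless another setting is named beside it. In simulated data, 200 of the 17059 probe sets were changed. The fit recovered 47% of changes of 1 log2 unit and 99% of changes of 2 log2 units. Of its 152 calls, 6 were false. The simulated noise was independent between probe sets and arrays, with the same spread in both groups. These shares therefore check the fit and do not give its accuracy on these arrays.

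Genes were named from a platform annotation of 2016, updated through gene identifiers with the RefSeq gene table of the TAIR10.1 assembly. That annotation lists 14016 probe sets, of which 13513 have 1 gene and 503 several. The other 8794 are unnamed here. Of the single-gene probe sets, 13436 matched a locus. Where a gene had several probe sets, lists used the one with the highest mean. The array build is not named in the sources used here, so no coordinates are given.

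There were 25 gene lists with 476 genes, fixed before the data were examined, and 70 of those genes had a named single-gene probe set. The 8 MYB targets of miR159 in the first list, 3 other proposed targets, 5 TCP targets of miR319 and both jasmonate lists had none, so their transcripts were not analysed here, and neither miR159a itself nor its targets checks the group labels. Transcripts with a site complementary to miR159a were not analysed here. Lists with at least 3 tested members were compared with the other probe sets by camera with a preset correlation of 0.01, adjusted over the 8 lists tested. The minimum of 3 was chosen after the coverage of the annotation was seen. On simulated data, 3 of 100 unchanged lists of 12 and 100 of 100 lists shifted by 1 log2 unit passed an unadjusted p of 0.05. The simulated probe sets were drawn independently of each other, so this does not check the preset correlation for lists whose members vary together.

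The genes named were, by a rule set before the data were examined, up to 15 with the largest rise and 15 with the largest fall among called single-gene probe sets whose overexpressor values all lay beyond all wild-type values, and up to 4 members of each list with the smallest p. All tested members of the mature pollen and gibberellin lists are named as well. Other genes are named as chosen after their values were seen.

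The letters were checked for pairing. Deviations from the group means correlated between the arrays sharing a letter with r = 0.57 for a, 0.36 for b and 0.38 for c, over probe sets. All 6 arrays correlated best with their own letter, against at most 0.10 for any other letter. Deviations within a group cancel out, so a high correlation for the same letter in itself lowers those for other letters. The letters also allow few matchings, so this check does not establish the pairing. For the fit with a block, the letters were taken as pairs as an assumption. The comparison without a block was kept, as set beforehand, and the fit with the letter as a block is given where it differs.

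Alternatives were quantile normalisation, median centring, pseudocounts of 1 and 64, no filter, a filter of 50%, an intensity trend, array weights, the replicate block, each array left out in turn, an estimated correlation in the list tests and the mean of a gene's probe sets. Leaving out both arrays lettered a was added after the data were seen.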

Results

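Stage 15 flowers of 3 wild-type Columbia samples and 3 samples overexpressing miR159a, a microRNA that pairs with transcripts of MYB transcription factors, were profiled on 1 array each. The median signal of the arrays lay between 85.2 and 96.9. The comparison asked which transcripts differ in flowers when miR159a is overexpressed.

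Transcripts of mature pollen fell in the overexpressor. Of 12 tested members of the mature pollen list, which holds 39 genes, 9 fell, 0 rose and 3 did not pass the test. The receptor-like kinase gene ANX2, which maintains the wall of growing pollen tubes, fell by 3.28 on the log2 scale (SE 0.44, n = 3 per group, limma adjusted p = 0.0119). Its signal was 338 ± 139 (SD, n = 3) in wild type and 22.8 ± 23.8 in the overexpressor. With a pseudocount of 64 the log2 fold change of ANX2 was -2.19. ANX1, its close relative, fell by 1.69 (SE 0.30). The receptor-like kinase genes AT4G39110, listed as BUPS1, and AT2G21480, listed as BUPS2, fell by 3.19 and 1.90.

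The leucine-rich repeat extensin genes of pollen, AT1G49490 (LRX9), AT3G19020 (LRX8), AT2G15880 (LRX10) and AT4G33970 (LRX11), all fell, with log2 fold changes of -3.67, -3.57, -2.80 and -2.19, and the pollen actin gene ACT12 fell by 1.82. The overexpressor signals of ANX1 and ACT12, 3.67 and 7.20, lay below the pseudocount, so their falls are understated. The MADS-box genes AGL66, AGL104 and AGL65, which act in maturing pollen, had log2 fold changes of -0.91, -0.77 and -0.12 with adjusted p of 0.187, 0.231 and 0.966. For AGL66 and AGL104 the overexpressor signals, 14.1 and 10.9, also lay below the pseudocount, so their changes are understated as well. Adjusted over the list alone, 11 of the 12 members fell, AGL65 being the exception. The list median was -2.05, and camera placed the list below the other probe sets with adjusted p = 4.18e-19. The adjusted p was 0.116 with an estimated correlation. With pseudocounts of 1 and 64 the median was -3.29 and -1.23. The median was -3.04 between the arrays lettered a, -1.46 between those lettered b and -1.79 between those lettered c.

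**Figure D1:**
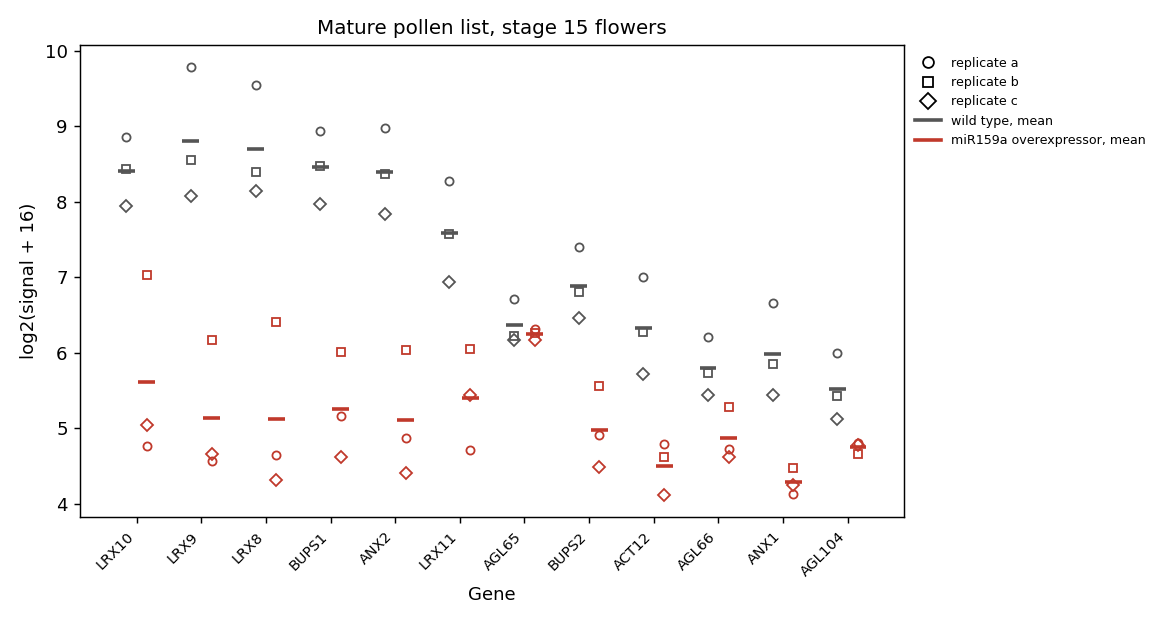
The log2(signal + 16) of the 12 tested mature pollen genes is plotted for each array, with wild type in grey, the miR159a overexpressor in red, a marker for each replicate letter and a line at each group mean. The group means differ by up to 3.67 log2 units at LRX9 and by 0.12 at AGL65.

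The falls extended far beyond the fixed list. Of 17059 probe sets, 370 were lower and 23 higher in the overexpressor at an adjusted p under 0.05, and 222 and 14 of them name 1 gene. In all 393 the overexpressor arrays did not overlap the wild-type arrays, a separation shown by 14.7% of all tested probe sets against 10% by chance. Among the called probe sets this separation follows largely from the selection by the test and is no separate support. Among the calls, 369 had changed at least 2-fold, 354 down and 15 up, and 127 had fallen at least 8-fold. The median log2 fold change of all tested probe sets was 0.04. With the letter as a block, 570 probe sets were lower and 71 higher, and they included the 370 and the 23. Without wild-type replicate b, 30 were lower and 0 higher.

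Of the 15 largest falls, AT3G26110 fell by 4.29 (SE 0.65, adjusted p = 0.0164), from a signal of 1987 ± 882 to 117 ± 126 (SD, n = 3). AT3G17060, AT5G07430 and AT3G05610, which encode pectinesterases, fell by 4.26, 4.05 and 4.05. AT3G07820, a polygalacturonase gene, fell by 4.08. RALFL26, a gene for a RALF-like peptide, fell by 4.24, and AT5G47000, a peroxidase gene, fell by 4.23. AT4G02250, AT1G54070, AT1G04470, AT3G28750, AT3G28830 and AT3G62180 fell, with log2 fold changes from -4.11 to -3.92, and AT5G61720 fell by 4.2. AT2G43620, of the chitinase family, fell by 3.98 with the smallest standard error of the 15 (SE 0.32, adjusted p = 0.00458).

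QQS, a gene found only in Arabidopsis thaliana that affects starch content, rose by 3.45 on the log2 scale (SE 0.50, adjusted p = 0.0139), from a signal of 45.1 ± 39.7 to 641 ± 389 (SD, n = 3). The peroxidase genes AT4G11290, AT5G19880 and AT3G03670 rose 4.94-fold, 4.29-fold and 2.42-fold. ADPG1, a polygalacturonase gene that acts in pod and anther opening, rose by 1.60 (SE 0.19, adjusted p = 0.0107), from 10.9 ± 2.25 to 66.9 ± 17.9. The wild-type signal of ADPG1 lay below the pseudocount, its log2 fold change was 2.50 with a pseudocount of 1 and 0.80 with 64, and it was not tested where the lowest 50% was left out. OCT1, an organic cation transporter gene, rose by 1.46, and the sugar transporter gene SWEET3 by 1.12. CES, a bHLH factor gene of the transmitting tract of the pistil, rose by 0.79, and GLC, which acts in fertilisation, by 0.88. AT1G56100, AT4G36770, SBT4.13, scpl47 and AT3G43270 rose by 1.25, 1.19, 0.93, 0.92 and 0.75.

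**Figure D2:**
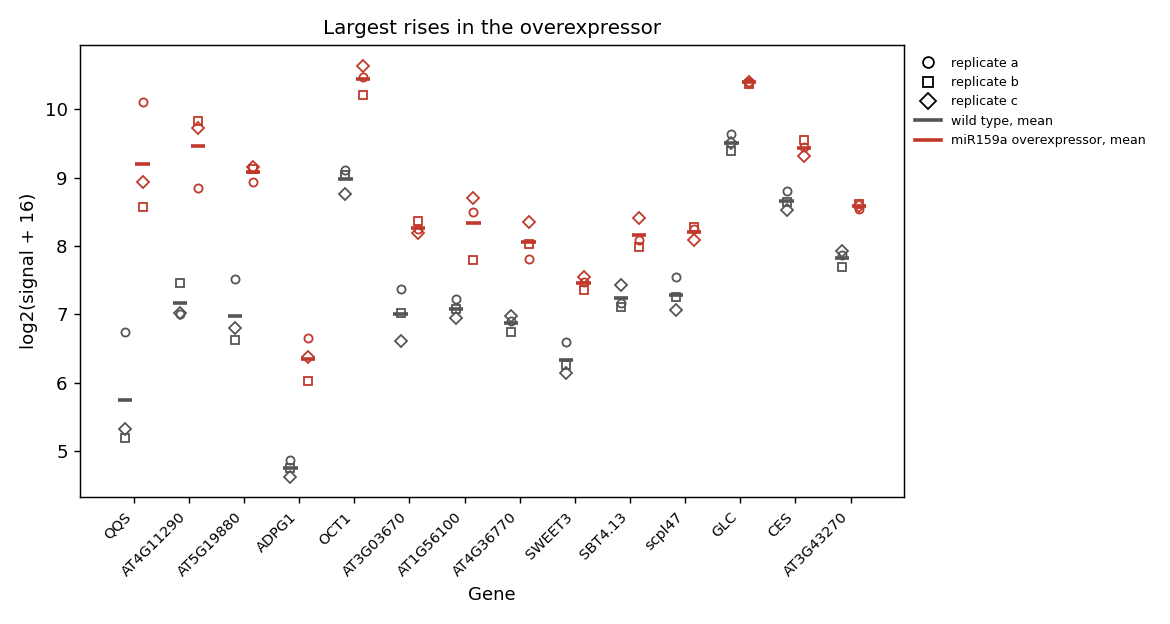
The log2(signal + 16) of the 14 single-gene probe sets called higher is plotted for each array, with wild type in grey, the miR159a overexpressor in red, a marker for each replicate letter and a line at each group mean. The overexpressor arrays lie above the wild-type arrays for each gene, by 3.45 log2 units at QQS and 0.75 at AT3G43270.

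The gibberellin list, read from only 5 of its 31 genes, shifted upwards as a set. Of these 5 tested members 0 passed the test, over all probe sets or adjusted over the list alone. The list median was 0.36, with camera adjusted p = 0.0115 and adjusted p = 0.116 with an estimated correlation. The shift holds for those 5 genes and not for the whole list. With a pseudocount of 64 the median was 0.23. The gibberellin receptor genes GID1A, GID1B and GID1C had log2 fold changes of 0.64, 0.36 and 0.09, the F-box gene SLY1 0.42 and the protease gene CP1 0.35.

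The senescence and cell death list, read from 3 of its 17 genes, shifted downwards with a median of -0.59. Camera gave adjusted p = 0.00108, and adjusted p = 0.116 with an estimated correlation. With pseudocounts of 1 and 64 the median was -1.05 and -0.25. Of its members, 0 passed over all probe sets, and adjusted over the list alone 2 fell. The transcription factor gene WRKY53 had a log2 fold change of -1.69 (SE 0.35, adjusted p = 0.0596, and 0.0221 with the letter as a block), SAG101 -0.59 and WRKY6 -0.37. For WRKY53 the log2 fold change was -2.29 with a pseudocount of 1 and -0.99 with 64, and its adjusted p ran from 0.00331, without overexpressor replicate b, to 0.228 over 15 alternatives, 3 of which passed. In the flavonoid list (4 tested, median -0.33, adjusted p = 0.133) 0 passed over all probe sets and 1 fell adjusted over the list alone, namely UF3GT, an anthocyanin glycosyltransferase gene. It had a log2 fold change of -1.81 (adjusted p = 0.0732, and 0.0179 with the letter as a block), against -0.39 for DFR, -0.26 for UGT78D2 and 0.34 for UGT78D1. The adjusted p of UF3GT ran from 0.0170 to 0.249 over 16 alternatives, 3 of which passed.

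Among auxin-responsive genes, GH3.3, which conjugates auxin to amino acids, fell by 1.03 (SE 0.19, adjusted p = 0.0332), and WES1 had a log2 fold change of -0.57 (adjusted p = 0.319). Of these 2 tested members, 1 fell over all probe sets and 2 fell adjusted over the list alone. In the secondary wall and anther opening list, ADPG1 rose and GUT2 had a log2 fold change of 0.12, which gave 1 of 2 members both over all probe sets and adjusted over the list alone.

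The photosynthesis, carpel and ovule, cell division and reference gene lists did not pass the test. Green tissue was read from 7 photosynthesis genes, with a median of 0.23 and camera adjusted p = 0.187, including LHCB4.2 at 0.35, PSAN at 0.30, PSBY at 0.24 and PSAE-1 at 0.23. The 6 carpel and ovule genes had a median of 0.10 (adjusted p = 0.293), with NGA2 at 0.37, ALC at 0.32, NGA4 at 0.15 and NGA1 at -0.13. The 3 cell division genes had a median of -0.22 (adjusted p = 0.152), with AUR2 at -0.52, AUR1 at -0.22 and PRL at 0.05. The 4 reference genes had a median of 0.13 (adjusted p = 0.367), with AT4G34270 at 0.33, AT2G28390 at 0.18, PEX4 at 0.08 and GAPC2 at -0.05. In these 4 lists 0 members passed, over all probe sets or adjusted over the list alone.

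The other lists with fewer than 3 tested members gave single values, and 0 of the members named here passed over all probe sets or adjusted over the list alone. The log2 fold change was 0.45 for BAN of early seed, 0.13 for ATHSP22.0 of heat shock, -0.05 for STZ of touch and handling and 0.48 for the clock gene GI. It was -0.25 for PHV and -0.02 for SMZ, which other microRNAs target, and -0.09 for SE and 0.04 for DDL of the small RNA machinery. The probe sets of the tapetum (4), sperm cell (1), floral organ identity (2) and defence (1) lists lay below the filter and went untested. The filter uses the mean over both groups, so a fall in the overexpressor can itself take a probe set below it. The sperm cell probe set, MGH3, was named after its values were seen. Its signal was 44.2 ± 30.5 (SD, n = 3) in wild type and 4.73 ± 3.96 in the overexpressor. Its log2 fold change was -1.44 (SE 0.34), without a test. The log2 fold changes in the other untested lists ran from -0.62 to 0.53.

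**Figure D3:**
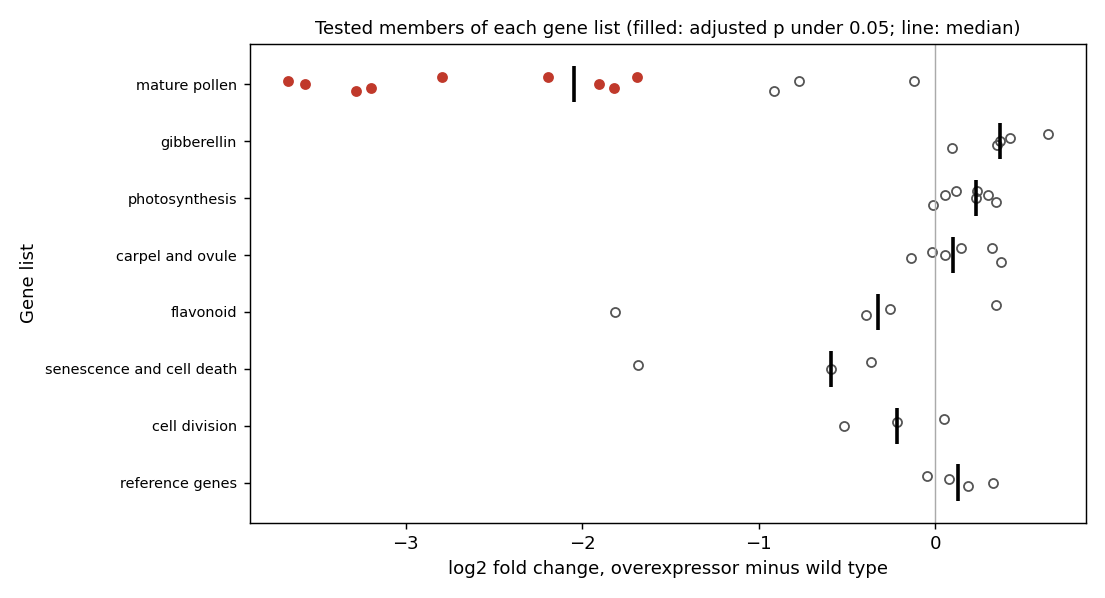
Each point is the log2 fold change, overexpressor minus wild type, of a tested member of the 8 gene lists with at least 3 tested members, filled where the adjusted p over all probe sets was under 0.05, and the line is the list median. The filled points are the 9 mature pollen genes that fell, and the medians of the other lists lie between -0.59 and 0.36.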

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

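The test of the control ratios was chosen after the result was seen. The control probe set for 25S ribosomal RNA, which no comparison used, read 3079.6 in overexpressor replicate a against 11.1 to 32.6 in wild type and 29.6 and 51.2 in the other overexpressor arrays.

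The arrays lettered a stood apart from the others in both groups. The second principal component, with 29.7% of the variance, separated them from the arrays lettered b and c, while the first, with 48.0%, separated the groups. If RNA integrity or labelling set them apart, signal ratios of the 5' to the 3' end of control transcripts would differ too. For actin the ratio was 0.656 and 0.653 on the arrays lettered a and at most 0.463 elsewhere, and for ubiquitin 0.807 and 0.886 against at most 0.560, while for GAPDH the lowest a ratio was 0.932 times the highest of the others. The middle of the 3 quotients was 1.41, which goes with a difference in RNA integrity or labelling. The actin and ubiquitin ratios were raised on the a arrays of both groups, but the high 25S ribosomal RNA reading was not shared. That reading was 19.3 in wild-type replicate a. A biological difference between the lettered samples stays open as untested.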

How the results depend on the processing

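Leaving out both arrays lettered a was chosen after the data were seen. No direction reversed among the 34 called genes named by the rule and the 3 lists called. Other called probe sets, among them ANX1, BUPS2, LRX10, LRX11 and ACT12, were not followed singly. The median of the mature pollen list ran from -3.29 to -1.23, that of the gibberellin list from 0.23 to 0.48 and that of the senescence and cell death list from -1.05 to -0.25, and the adjusted p of the mature pollen list stayed under 0.05 except with an estimated correlation. That setting called 0 lists instead of 3, since all 3 medians (-2.05 for mature pollen, 0.36 for gibberellin, -0.59 for senescence and cell death) had adjusted p = 0.116. Against 23 probe sets higher, 370 lower and 369 changed at least 2-fold, a pseudocount of 1 gave 13, 209 and 217, and a pseudocount of 64 gave 244 changed at least 2-fold. Leaving out the lowest 50% gave 180 lower, 185 changed at least 2-fold and 1 list called, where fewer probe sets were tested. The gibberellin list and the senescence and cell death list kept fewer than 3 members there and were not tested. Array weights gave 39 higher and took UF3GT and WRKY53 past the threshold (adjusted p = 0.0170 and 0.0266), as did leaving out overexpressor replicate a for UF3GT (0.0328) and b for WRKY53 (0.00331). The replicate block gave 71 higher and 570 lower, took UF3GT and WRKY53 past the threshold and changed no other call of a named gene or list. Leaving out both arrays lettered a gave 9 higher, 84 lower and 93 changed at least 2-fold. With 1 array left out, the higher count ran from 0 to 16, the lower count from 30 to 386, the count changed at least 2-fold from 30 to 394 and the lists called from 3 to 5. The counts of higher, lower and at least 2-fold were 13, 232 and 243 without wild-type replicate a, 0, 30 and 30 without wild-type replicate b, 14, 196 and 207 without overexpressor replicate a (with 5 lists, photosynthesis and flavonoid joining), and 5, 166 and 171 without overexpressor replicate c. Without wild-type replicate c 9 were higher. At an unadjusted p under 0.05 limma gave 521 higher and 978 lower on all 6 arrays, of 17059 probe sets tested. A share of 0.05 of those tested would pass without any change, spread over both directions. The 521 rises lie not far above that level and are no sign of a broad rise. Of these 34 genes, 17 stayed past the threshold with a pseudocount of 1, 25 with no filter, 6 without both arrays lettered a and 34 with the block. With 1 array left out, 16 stayed without wild-type replicate a, 1 without wild-type replicate b and 11 without overexpressor replicate a. Beyond the smaller number of arrays or probe sets tested, the cause was not tested. The medians of the miR159 MYB targets and of transcripts with a complementary site were not run. Dim probe sets are limited by the pseudocount, since their falls end at the floor of the scale.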

Other observations

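The tests of array scaling, of pollen number, of floral stage, of the rises and of gene families, and the limits that define bright and level falls, were chosen after the result was seen. Some falls were level across the overexpressor arrays. With a spread under 0.5 log2 units between those arrays, a mean overexpressor signal over 30 and a log2 fold change of at most -1, there were 30 such probe sets, 21 with 1 gene. Their small spread in the overexpressor follows from the first of these limits and is no separate result. The genes named here were chosen after their values were seen. The peroxidase gene AT5G64120 fell from 518 ± 83.0 to 54.8 ± 12.1 (SD, n = 3, limma adjusted p = 0.00291), SP1L4 from 834 ± 232 to 105 ± 11.1 (adjusted p = 0.00396), the chitinase family gene AT2G43610 from 335 ± 89.4 to 82.6 ± 12.4 (adjusted p = 0.0107) and the auxin-conjugating gene GH3.3 from 409 ± 92.9 to 188 ± 3.01 (adjusted p = 0.0332).

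Genes of RALF-like peptides, small secreted signals, were tested for over-representation among the falls. Of 36 symbol families with at least 5 tested members, RALFL had 3 of 10 lower against 222 of 9491 named probe sets (Fisher's exact test, one-sided, p = 0.00134, adjusted p = 0.0483). RALFL26, RALFL25 and RALFL18 fell by 4.24, 3.73 and 1.25, with no overlap between the 3 arrays of each group, as for every called probe set. RALFL25 and RALFL26 are neighbours whose probe sets could read close copies, and with the pair counted once 2 of 9 were lower and the adjusted p was 0.628, so the result rests on that pair.

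Among 50 falling probe sets with a wild-type mean over 1000, of which 0 are in the mature pollen list, the median signal was 5.73% of the wild-type mean in overexpressor replicate a, 16.3% in b and 1.96% in c, and b was highest of the overexpressor arrays for 291 of the 370 falls. These 50 also varied between the wild-type arrays, with medians of 137% in a, 88.4% in b and 72.4% in c. In overexpressor replicate c the median signal of the 50 was 33.3 and 11 of them lay at or below the pseudocount of 16, so the share there is no exact level and the order of overexpressor a and c is left open.

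For the fall of the mature pollen list, the median of all tested probe sets was 0.044 (interquartile half-width 0.14) against -2.05 for the list. The signals had been scaled beforehand, which by itself holds the overall median close to no change. The gap between the list and that median still argues against scaling of the arrays as the whole cause. With 1 factor per array, all probe sets would move nearly alike. Fewer pollen grains in the sampled flowers cannot be told apart from lower levels within each grain. Fewer grains would give the members 1 factor per array, and the interquartile range of their log2 ratios reached 2.27 in an overexpressor array, but 8 of the 12 members had a mean overexpressor signal over the pseudocount, too few to decide. Among the 50 bright falling probe sets, outside the list, that range was 0.88 in replicate a, 0.54 in b and 1.0 in c, which decides nothing either, since they were picked as bright called falls and some lay at the floor in c. Flowers of another stage cannot be told apart either, because 6 carpel and ovule genes with a median of 0.10 (SD 0.20) are too few, and an effect of miR159a itself stays open.

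The rises could follow from a loss of pollen RNA that raises all other transcripts on scaled arrays. The median log2 fold change of the 16689 probe sets not called lower was 0.049, with an interquartile half-width of 0.14, while the smallest called rise was 0.75. This argues against that loss as the whole cause, and no other explanation was tested.

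Falling genes may lie near each other on the chromosomes. Of 221 falling genes, 22 had another within 3 genes, against a median of 8 and a 95th percentile of 16 in 10000 random draws from the 9365 genes tested (p = 0.0051, permutation test, one-sided). They included the chitinase family genes AT2G43590, AT2G43610 and AT2G43620, the RALF-like genes RALFL25 and RALFL26 and the pectinesterase genes AT5G07420 and AT5G07430. Probe sets that read close copies cannot be told apart from clustering, because leaving out the s and x types removed no falling gene and left the count at 22.

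Splits of the 6 arrays into 3 and 3 were too few for a share under 0.05, since there are 10. In 1 of the 10, the real one, as many probe sets were higher (23), lower (370) or changed at least 2-fold (369). The highest count among the other splits was 0 for each. In 1 of the 10, again the real one, as many lists were called (3, highest of the others 2). Most of the other splits called 1 or 2 lists while calling 0 probe sets. At the preset correlation, camera thus also called lists where the groups were mixed, and 3 called lists stand little above that. The real split is among 4 that part all 3 letter pairs, and the other 3 of these called 0 probe sets with limma. Every split other than the real one mixes the groups. The group difference then adds to the spread within each side, which makes 0 calls likely there. These counts therefore give no level of chance.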
